A study of Mus musculus with 8 samples.

How the data were processed

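Naive CD8+ T cells of 8 samples, 5 labelled Furin KO and 3 labelled WT, were profiled by RNA sequencing of total RNA, per the labels' protocols. The authors deposited 1 table of raw whole-number counts per gene, with 55573 mouse Ensembl gene IDs and 1 column per sample. Per the submitters' processing notes, the tools named are FastQC, Trim Galore, STAR and DESeq2 1.24.0, with the genome build GRCm38. Which program counted reads, the annotation, the handling of reads that match several genes and the strand setting are not given in the sources used here. Genes with near-identical copies and genes that overlap others are therefore uncertain. Columns were matched to samples by title. The column of Furin KO replicate 4 stands among those of the WT libraries, and its label was used. Gene symbols and coordinates came from GENCODE M21 on GRCm38: 55394 IDs matched and 179 did not.

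From the deposited counts, edgeR 4.0.16 (limma 3.58.1, R 4.3.3) was run with TMM factors, the filterByExpr filter by genotype and the quasi-likelihood test of genotype without covariates, two-sided. 12500 genes were tested, holding at least 99.9% of the counts of each library. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. CPM values, counts scaled to a common library size, use the TMM-scaled library sizes. The common biological coefficient of variation was 0.202. Furin and each named gene were also given an exact two-sided permutation test on log2(CPM + 1), whose smallest p is 0.0179. Replicate numbers follow accession order and were not used to pair libraries. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom of their counts was at least 10.9. Clustering of the libraries on this chi-square into 3 sets, a number chosen after seeing the data, put both genotypes in each set. The 7 pairs within sets had values of 10.9 to 16.6 and the 21 pairs between sets 16.7 to 38.3. No label names a batch, but each set is a run of consecutive samples by title, which the clustering did not use.

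37 gene lists were fixed before the data were examined. 36 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 36. The tests were repeated with an estimated correlation and with fry. Named genes followed a rule fixed at the same time. Furin comes first. Then come up to 12 genes with the largest rise and 12 with the largest fall among those with adjusted p under 0.05, mean CPM of at least 5, groups that do not overlap and an established symbol that is not a receptor segment. Up to 4 members of each list follow, and, where fewer than 6 genes passed in a direction, the genes of lowest unadjusted p up to 6 are given as values. B430306N03Rik lies outside this rule by its symbol and is named because only 4 genes passed. Some genes that the rule names are not reported here. Genes given only as levels were chosen after their values were seen.

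The test was tested on simulated data: counts for 12500 genes were drawn from the real means and library sizes, with 200 genes changed 1.5-, 2- or 4-fold and a list of 20 further genes changed 1.3-fold. In this comparison of Furin KO with WT it recovered 41.8% of genes changed 1.5-fold, 82.1% of genes changed 2-fold and 83.3% of genes changed 4-fold, and 5 of the 20 list genes, with 9 false calls of 152. Genes were drawn independently, without library sets, and changed genes only from those above a low minimum of mean CPM. The real comparison called 4 genes, so with 152 calls the adjusted threshold was easier to pass, and real recovery may be lower.

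Alternatives set before the data were examined were other size factors (RLE, library size alone), no filter beyond 1 count or a CPM of 1 in 3 samples, DESeq2 1.42.0, limma-voom, age as a factor, the 8-week libraries alone, exclusion of receptor segments and mitochondrial genes, and each library left out. Alternatives chosen after seeing the data left out Furin KO replicate 5 with WT replicate 1, used limma-voom with quality weights, added 1 surrogate variable (sva 3.50.0), or added the level of early response genes, low where Fos lay far under its median, or the library set as a factor. Total counts of 11308220 to 21040431 per library set the precision, and confidence intervals on ratios of counts cover counting error only.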

Results

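RNA was sequenced from naive CD8+ T cells, the resting cytotoxic lymphocytes that have not yet met their antigen, of male C57BL/6 mice. The cells came from spleen and lymph nodes, were enriched for CD8a with a magnetic kit and were then sorted by flow cytometry. The 8 libraries comprised 5 labelled Furin KO and 3 labelled WT. WT replicate 1 and Furin KO replicate 1 came from mice of 7 weeks and the other 6 libraries from mice of 8 weeks. Total counts over genes ranged from 14463450 to 19159021 in the WT libraries and from 11308220 (Furin KO replicate 5) to 21040431 in the Furin KO libraries. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these samples, which may be partly technical.

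The cells carried the transcripts of naive CD8+ T cells in both groups. Cd8a, the alpha chain of the CD8 co-receptor, stood at 1752 ± 111 CPM (counts scaled to a common library size; mean ± SD, n = 5) in the Furin KO libraries and 1584 ± 180 CPM (n = 3) in WT. Tcf7, a transcription factor of naive and stem-like T cells, stood at 2262 ± 158 and 2233 ± 224 CPM. Cd44, which is high on antigen-experienced cells, was between 0.313 and 2.72 CPM in every library, and Cd4 was at most 0.892 CPM. Of other cell types, the B cell genes Cd79a and Ms4a1 reached at most 1.34 CPM and 0 counts, and the macrophage gene Lyz2 at most 0.910 CPM. Cd79b, another B cell receptor gene, was at 22.8 ± 3.34 and 23.4 ± 3.98 CPM, and Ighm, the immunoglobulin mu chain, was at 745 ± 67.0 CPM in the Furin KO libraries and 706 ± 111 CPM in WT. These level genes were chosen after the data were seen.

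The comparison asked how the transcriptome of naive CD8+ T cells differs without FURIN, a protease that cleaves precursor proteins to their active forms in the secretory pathway. The targeted gene is given first. The count of Furin (ENSMUSG00000030530, GRCm38 chromosome 7, 80388585 to 80405436, minus strand) was not lower in the libraries labelled Furin KO. It was 69.3 ± 11.8 CPM (n = 5) there and 63.6 ± 5.7 CPM (n = 3) in WT. The log2 fold change was 0.12 (95% interval -0.15 to 0.40; exact two-sided permutation p = 0.5 over 56 arrangements, of which the smallest possible is 0.0179). The 3 WT libraries had 57.0, 66.8 and 66.9 CPM, and the 5 Furin KO libraries had 63.5, 86.4, 62.2, 58.0 and 76.6 CPM in replicate order. Whole-gene counts do not show which exons carry the reads, and the labels do not state which part of the gene was removed, so this count alone does not check the labels. Every direction below is drawn between libraries labelled Furin KO and libraries labelled WT. An annotated antisense gene, Gm44851, overlaps the start of Furin, and the strand setting of the counting was not given. Of the other proprotein convertases, Pcsk7 was at 98.3 ± 13.3 CPM in the Furin KO libraries and 93.1 ± 4.09 CPM in WT, and Mbtps1 at 283 ± 23.6 and 291 ± 10.6 CPM. Pcsk1 had a log2 fold change of -0.59 that did not pass, and 0 of the 5 tested members of the list passed.

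4 genes differed between the genotypes, 3 of them higher and 1 lower in the libraries labelled Furin KO. Tspan9, a tetraspanin membrane protein, fell from 54.4 ± 13.2 CPM in WT (n = 3) to 17.8 ± 3.6 CPM in Furin KO (n = 5). Ly6a (Sca-1), a lipid-anchored surface protein that is raised on activated lymphocytes, rose from 23.4 ± 4.2 to 75.4 ± 19.5 CPM. Socs3, an inhibitor of cytokine receptor signalling through JAK and STAT proteins, rose from 236 ± 8.3 to 445 ± 70.0 CPM. B430306N03Rik, a protein-coding gene without an established name, rose from 15.2 ± 1.19 to 35.5 ± 8.30 CPM. All 5 Furin KO libraries lay beyond all 3 WT libraries at each of these genes.

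**Figure D1:**
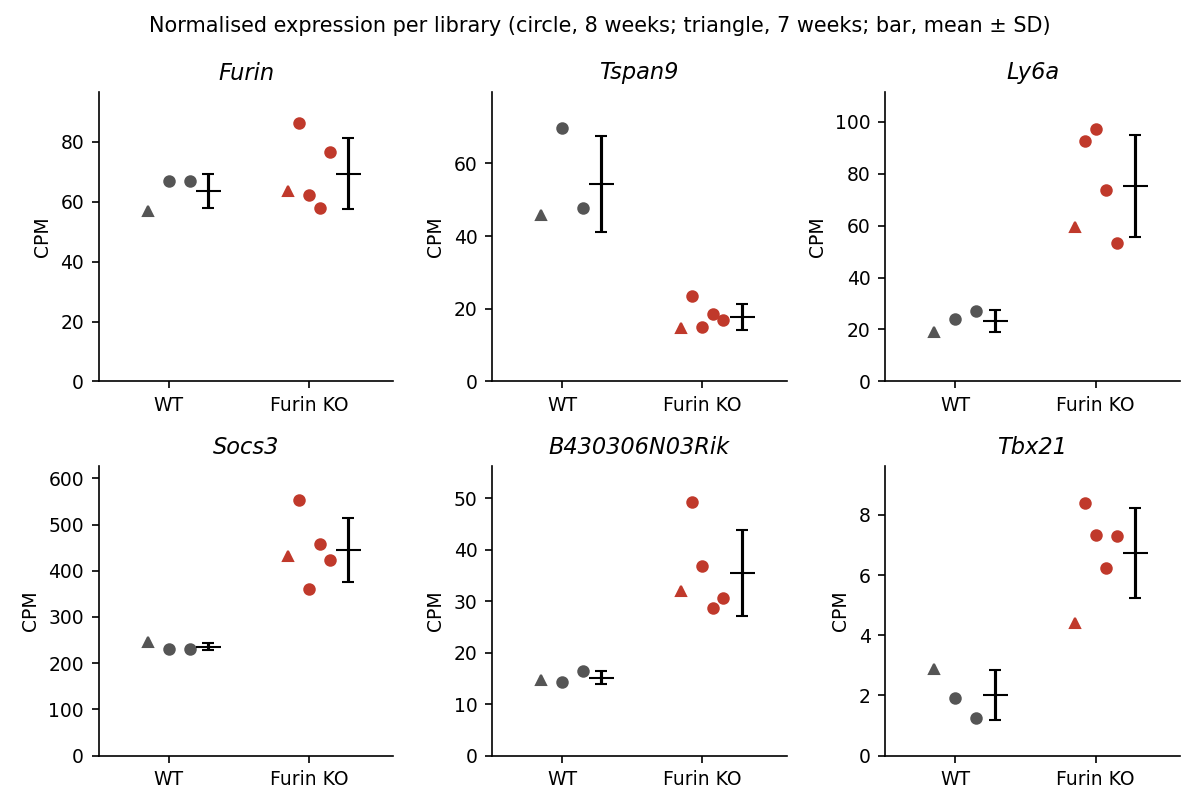
Normalised expression in CPM of Furin, the 4 genes past the threshold and Tbx21, 1 point per library (circles 8 weeks, triangles 7 weeks), with the mean and SD of 3 WT and 5 Furin KO libraries. At Tspan9 the Furin KO libraries lie between 14.7 and 23.6 CPM and the WT libraries between 45.9 and 69.7, while at Furin the groups overlap.

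By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12500 genes, the log2 fold change of Tspan9 (ENSMUSG00000030352, chromosome 6, 127961396 to 128143594) was -1.61 (SE 0.17, adjusted p = 0.000359). That of Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031) was 1.69 (SE 0.19, edgeR adjusted p = 0.000524). For Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047) it was 0.92 (SE 0.12, edgeR adjusted p = 0.00164), and for B430306N03Rik (ENSMUSG00000043740, chromosome 17, 48316141 to 48327024) 1.23 (SE 0.18, edgeR adjusted p = 0.00661). 401 genes had an unadjusted p under 0.05, 201 higher and 200 lower, where 625 would be expected with no difference, and 706 did with 3 sets of similar libraries as a factor. 363 genes (2.90%) had groups that did not overlap, where chance gives 3.57%. DESeq2 called 12 genes higher and 2 lower, the 4 above among them, edgeR without a filter on low counts called 25 and 13, and edgeR with those sets as a factor called 8 and 4. B430306N03Rik did not pass in the 8-week libraries alone, without WT replicate 1 (alone or together with Furin KO replicate 5) or without WT replicate 2, whereas the other 3 genes passed in all 22 alternatives run on them.

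Further genes named by the rule did not pass in the edgeR fit without covariates, from which their values and adjusted p are given, and some passed in other fits. Among those higher in the Furin KO libraries, Tbx21, the transcription factor T-bet of effector and memory T cells, had 6.73 ± 1.501 CPM against 2.02 ± 0.826 (log2 fold change 1.74, edgeR adjusted p = 0.171). Iigp1, an interferon-induced GTPase, had 39.0 ± 10.7 against 19.0 ± 2.91 CPM (1.04, edgeR adjusted p = 0.156). Chst11, a chondroitin sulfotransferase, had 11.7 ± 3.23 against 4.56 ± 1.31 CPM (1.37, edgeR adjusted p = 0.156). Among those lower, Lrig1, a membrane protein that restrains growth factor receptors, had 35.3 ± 2.62 against 54.7 ± 1.87 CPM (-0.63, edgeR adjusted p = 0.0694). Rarg, a retinoic acid receptor, had a log2 fold change of -0.37, and Ahnak, a large scaffold protein, -0.59 (edgeR adjusted p = 0.667 and 0.690). Syce1, a protein of meiotic chromosomes, had 72 counts in the 3 WT libraries and 3 in the 5 Furin KO libraries, a ratio of 43.2 per sequenced count (exact 95% interval 14.2 to 214, counting error only). Its edgeR adjusted p was 0.476, and its counts in the WT libraries were 17, 41 and 14. A processed pseudogene, Gm29799, lies within Syce1 on the opposite strand, and Slc25a26 overlaps Lrig1 on the opposite strand. DESeq2 called Tbx21, Iigp1, Chst11 and Lrig1, edgeR without the filter on low counts called these and Ahnak, and edgeR with the library set as a factor called Iigp1, Chst11, Lrig1 and Ahnak. The fit without the filter also called Hspa1b and Dnajb1, at which the groups overlapped (exact two-sided permutation p = 0.214 and 0.286). A call by that fit alone is therefore weak evidence.

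The lists fixed before the data were examined gave 6 of 36 that differed, by camera at a preset correlation of 0.01, 3 higher and 3 lower. None of the 6 passed with the correlation estimated from these libraries, where the lowest adjusted p was 0.508, nor in the directional fry test (lowest adjusted p = 0.457). The mixed fry test, which asks whether genes of a list change in either direction, called 2 lists, cytokine and STAT5 (adjusted p = 0.0132) and effector and memory (adjusted p = 0.0372). Counts of passing list genes below are from the edgeR fit with the filter on low counts and without covariates. Without that filter, H2-Q6, Gbp2, Igfbp4, Irf4 and Bcl3 also passed over all genes as higher and Itgae, Hspa1a, Hspa1b and Dnajb1 as lower, beside the genes named above. DESeq2 also called H2-Q6 and Igfbp4 over all genes as higher (DESeq2 adjusted p = 0.00823 for each). All 20 tested genes of class I antigen presentation had fold changes above 0, with a median log2 fold change of 0.12 (camera adjusted p = 2.51e-06; adjusted p = 0.508 with an estimated correlation of 0.326). 0 of them passed over all genes and 1 passed adjusted over the list alone, H2-Q6, at 285 ± 25.9 CPM against 206 ± 27.3 (log2 fold change 0.47, edgeR adjusted p = 0.406). H2-Q6 has near-identical neighbours such as H2-Q4 (log2 fold change 0.24), so its reads are uncertain. Psmb9, a subunit of the immunoproteasome, had 0.22.

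The cytokine and STAT5 list was higher (camera adjusted p = 0.00887; adjusted p = 0.508 with an estimated correlation). 13 of its 20 tested genes had fold changes above 0 and 1 of them, Socs3, passed over all genes and adjusted over the list alone. Jak3, the kinase of the common gamma chain receptors, had a log2 fold change of 0.32 and Stat3 one of 0.17, and neither passed. The list did not pass without WT replicate 2. The type I interferon list was higher, with 23 of 36 genes above 0 and a median of 0.10 (camera adjusted p = 0.0139; adjusted p = 0.692 with an estimated correlation). 0 of its genes passed in either adjustment. Gbp2, an interferon-induced GTPase, had 0.47. This list did not pass without WT replicate 2, Furin KO replicate 3 or Furin KO replicate 4.

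The TGF-beta pathway list was lower (camera adjusted p = 0.0035; adjusted p = 0.508 with an estimated correlation). FURIN is known to process the TGF-beta precursor. 13 of its 17 tested genes had fold changes below 0, with a median of -0.11, and the summed expression of all listed genes, per library total without TMM factors, was 1901 ± 78.7 CPM in Furin KO (n = 5) against 2145 ± 60.6 CPM in WT (n = 3). Its exact two-sided permutation p was 0.0179, the smallest the design allows and the lowest of 37 list sums (0.661 adjusted over them), and Itgae alone made up -118 of the difference of -244 CPM. 0 genes passed over all genes and 1 passed adjusted over the list alone, Itgae, the integrin chain CD103 that TGF-beta induces. Itgae had 348 ± 40.0 CPM against 465 ± 58.1 (log2 fold change -0.42, edgeR adjusted p = 0.690), and another gene, Haspin, lies within it on the opposite strand. With the library set as a factor, chosen after the data were seen, the edgeR adjusted p of Itgae was 0.00670. Smad7, an inhibitor of TGF-beta signalling, had a log2 fold change of -0.25, Smurf1 one of -0.23 and Ski one of -0.17. The list mixes inhibitors such as Smad7 with induced genes such as Itgae, so its lower direction alone does not show weaker signalling.

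The cholesterol synthesis list was lower, with 17 of 22 genes below 0 and a median of -0.18 (camera adjusted p = 0.0139; adjusted p = 0.601 with an estimated correlation). 0 of its genes passed in either adjustment. Srebf2, the transcription factor of the pathway, had -0.20 and Sqle, an enzyme of it, -0.39. The list did not pass without WT replicate 2, Furin KO replicate 1 or Furin KO replicate 4. The heat shock list was also lower (camera adjusted p = 0.0139; adjusted p = 0.610 with an estimated correlation), with 12 of 14 genes below 0 and a median of -0.07. 0 genes passed over all genes and 2 adjusted over the list alone, Hspa1a (-1.56) and Hspa1b (-1.45), chaperones whose near-identical sequences share reads. Without the filter on low counts, edgeR called both over all genes, with an adjusted p of 0.000101 for the log2 fold change of Hspa1a and 6.82e-10 for the log2 fold change of Hspa1b, and also the log2 fold change of Dnajb1, a co-chaperone (adjusted p = 0.000197). At Hspa1a, Hspa1b and Dnajb1 the groups overlapped, with exact two-sided permutation p of 0.232, 0.214 and 0.286. WT replicate 1 had 46.8 CPM of Hspa1b and WT replicate 2 had 5.69. Without WT replicate 1 the list had an adjusted p of 0.684, and it also did not pass without Furin KO replicate 1, without Furin KO replicate 4, in the 8-week libraries alone or with age as a factor.

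**Figure D2:**
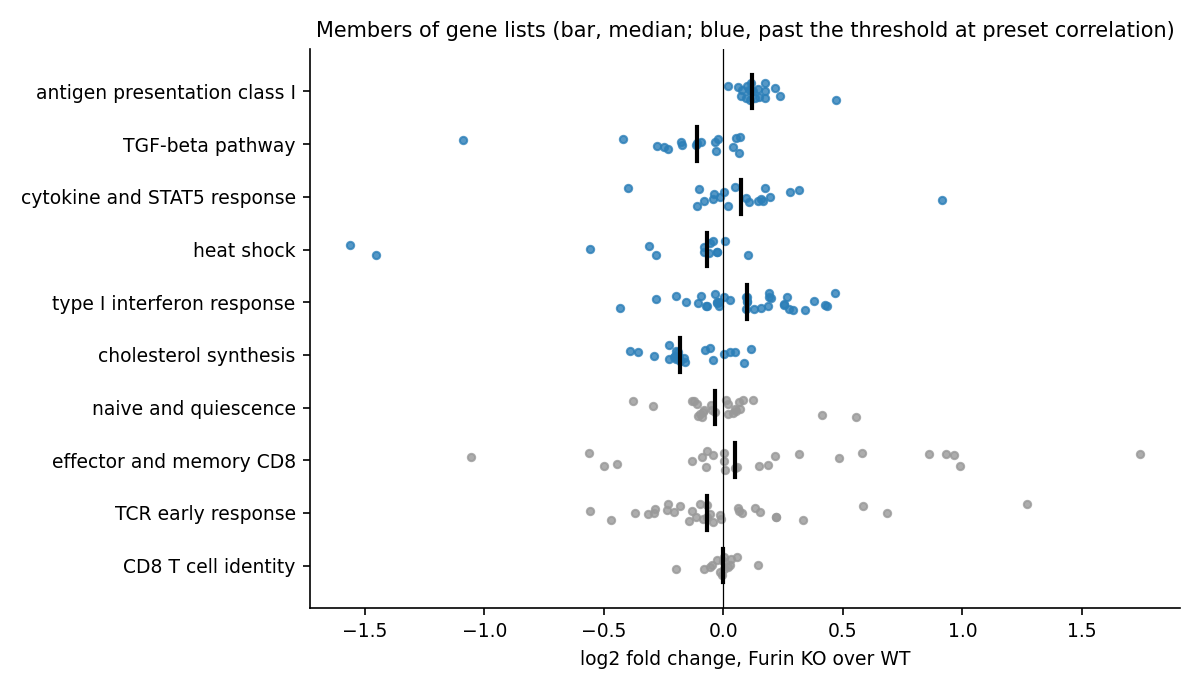
Log2 fold change of Furin KO over WT for each tested gene of the 6 lists past the threshold at a preset correlation (blue) and of 4 lists that were not (grey), with the median as a bar. The 20 class I antigen presentation genes all lie above 0, while the 15 genes of CD8 T cell identity have 7 above and 8 below 0.

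By camera, 0 lists of T cell state passed. In the naive and quiescence list 0 of 25 genes passed over all genes (camera adjusted p = 0.950), with Igfbp4 at a log2 fold change of 0.56 (past the threshold adjusted over the list alone) and Il7r, the interleukin-7 receptor, at -0.29. In the effector and memory list 0 of 25 passed (camera adjusted p = 0.379), and adjusted over the list alone Tbx21 and Lgals1 (-0.44) did. The early response genes of T cell receptor stimulation gave 0 of 32 (camera adjusted p = 0.958), with Irf4 at 1.27 and Irf8 at 0.69. Among inhibitory receptors Ctla4 had 1.38 (0 of 9 passed, camera adjusted p = 0.105). In the NF-kB and TNF family list 0 of 22 passed over all genes, and Bcl3 (0.59) passed adjusted over the list alone. The substrates of FURIN, as transcripts, gave 0 of 20, 10 above and 10 below 0 (camera adjusted p = 0.627), and Itgae passed adjusted over that list alone. Cell cycle genes gave 0 of 32, glycolysis 0 of 20 and nuclear oxidative phosphorylation genes 0 of 39. Of the markers of other cell types, the lists of B cells, myeloid cells, dendritic cells, NK cells, gamma-delta T cells and CD4 or regulatory T cells gave 0 genes past the threshold. For CD4 and regulatory T cells the camera adjusted p was 0.338, and Izumo1r passed adjusted over that list alone (log2 fold change 0.50).

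The libraries also differed in ways that genotype did not follow. Fos, an immediate early gene, was at 144, 204 and 85.8 CPM in WT replicate 2, Furin KO replicate 2 and Furin KO replicate 3, and between 801 and 1075 CPM in the other 5 libraries. Dusp1, another early gene, was at 42.5, 56.2 and 36.2 CPM in those 3 libraries and between 227 and 386 in the others. By the pairwise distances of their counts the libraries fell into 3 sets, each with both genotypes: WT replicate 1 with Furin KO replicate 1 (both 7 weeks), WT replicate 2 with Furin KO replicates 2 and 3 (those low in Fos), and WT replicate 3 with Furin KO replicates 4 and 5. Each set is also a run of consecutive samples by title, which the distances did not use. In the first set (n = 1 and 1) Tspan9 had 14.7 CPM in Furin KO and 45.9 in WT, Ly6a 59.4 and 18.9, Socs3 431 and 245, and B430306N03Rik 32.1 and 14.6. In the second set (n = 2 and 1) Tspan9 had 19.4 and 69.7, Ly6a 95.1 and 24.2, Socs3 457 and 231, and B430306N03Rik 43.0 and 14.3. In the third set (n = 2 and 1) Tspan9 had 17.7 and 47.7, Ly6a 63.6 and 27.2, Socs3 440.4 and 231, and B430306N03Rik 29.6 and 16.5. With the set as a factor, chosen after the data were seen, edgeR called the 4 genes above, Iigp1 (adjusted p = 0.00670), H2-Q6 (0.00670), Chst11 (0.0201), Igfbp4 (0.0166) and Itgb3 (0.0222) as higher, and Itgae (0.00670), Lrig1 (0.0121) and Ahnak (0.0320) as lower. Itgb3, an integrin chain, lies outside the rule for named genes. With the early gene level as a factor, also chosen after the data were seen, edgeR called 4 genes higher and 2 lower, the 4 above together with Iigp1 and Lrig1. With age as a factor it called the same 4 genes, and in the 8-week libraries alone 2 higher and 1 lower.

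**Figure D3:**
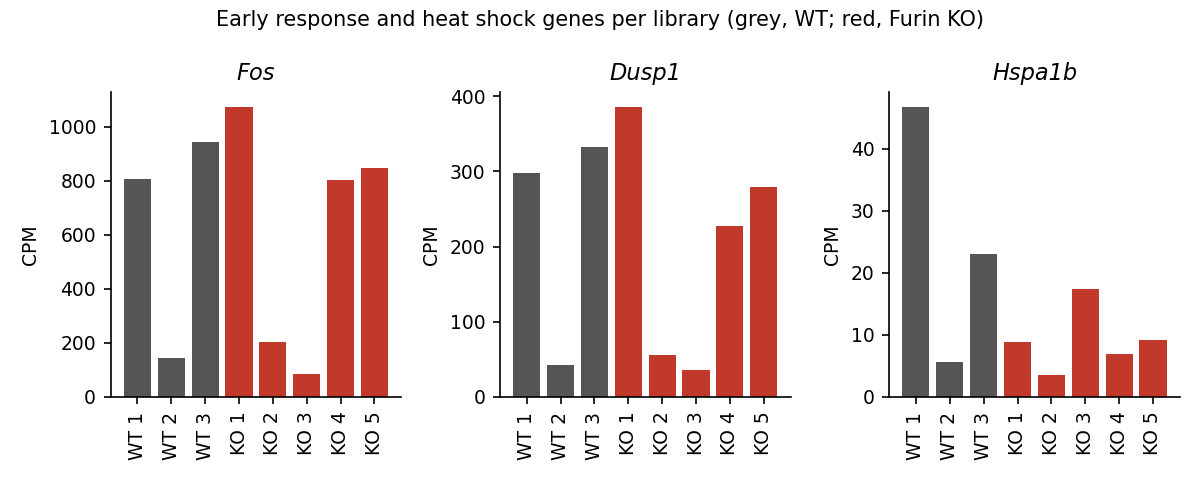
Expression in CPM of the early response genes Fos and Dusp1 and the heat shock gene Hspa1b, 1 bar per library (grey WT, red Furin KO). Fos lies at or below 204 CPM in 3 libraries of both genotypes and at or above 801 CPM in the other 5.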

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

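The tests of the Furin count and of the heat shock list were chosen only after those results were seen. In the 5 Furin KO libraries 5 of 49 values had 1 library far from the rest by Dixon's test, where chance gives about 2.45. Furin KO replicate 5 had the lowest total, 11.3 in units of 1e+06 counts, against 18.6 to 21.04 in the other 4, and stood alone on the first principal component (22.6% of the variance) at 66.7 against -15.2 to -2.84. Syce1 was at 0.264 CPM (3 counts) in this library and had 0 counts in the other 4. In Furin KO replicate 2, Chst11 was at 17.3 CPM against 9.10 to 11.2, and Il21r at 470 CPM against 350.0 to 379.

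The Furin count was not lower in the libraries labelled Furin KO, with a log2 fold change of 0.12. A candidate explanation is that the allele loses only a short part of the transcript: loss of the second exon, 335 bases or 8.04% of a Furin transcript, would change the count by -0.12, and the 95% interval of the fold change reaches down to -0.15. The labels do not name the exon, and no counts per exon were used here, so this cannot be told apart from an intact gene. All 8 libraries lay between 57.0 and 86.4 CPM of Furin, so a single wrong label does not hide a 2-fold loss. Without each library in turn, the 95% interval of the log2 fold change reached down to -0.26 at the lowest (without WT replicate 1). That bound was written knowing the Furin values, and a smaller hidden loss stays open. It does not show that the labels are right, since loss of a short part would barely move the count. 3 earlier forms of the wrong-label check placed each library at genes chosen without it. They had 7 (not WT replicate 2), 6 and 8 of 8 libraries on the side of their label. Furin KO replicate 4, whose column stands among the WT ones, lay nearer Furin KO at 4 of 4 genes called without it. A library off its side need not be mislabelled, since leaving it out can select genes at which it goes against the rest. These forms differ in their counts and rest partly on 3 to 5 called genes per fit, so no conclusion is drawn from them.

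The heat shock list was lower in the libraries labelled Furin KO, with a median log2 fold change of -0.07. Without WT replicate 1 its adjusted p was 0.684 and its median -0.02, so that library may account for the difference. Genotype stays open, since Hspa1b without that library still had a log2 fold change of -0.64, and so does age: that mouse was 7 weeks old, although Furin KO replicate 1, the other 7-week library, had 8.87 CPM of Hspa1b against 46.8.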

How the results depend on the processing

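Leaving out Furin KO replicate 5 with WT replicate 1, quality weights, the surrogate variable and the early response and library set factors were chosen after seeing the data. Tspan9, Ly6a and Socs3 passed in 22 of 22 alternatives and B430306N03Rik in 18. Over 41 named genes, 862 of 901 values kept direction and side of the threshold, 4 no longer passed, 33 newly passed and 2 reversed. Against 3 genes higher and 1 lower, no filter beyond 1 count gave 25 and 13 (37 of these 38 genes also pass the usual filter, and the cause was not tested), DESeq2 12 and 2, and library set as a factor 8 and 4. Lower genes numbered 2 with limma-voom, 2 with limma-voom quality weights and 2 with early response level as a factor. The surrogate variable gave 4 and 1. Against 6 lists, 0 passed with an estimated correlation and 0 by fry. With 1 library left out, lists ranged from 3 (without WT replicate 2 or Furin KO replicate 4) to 10 (without WT replicate 3), genes higher from 2 to 4 and genes lower from 1 to 1, and the Furin log2 fold change from 0.03 to 0.19. The log2 fold change of Hsp90aa1, at -0.28, ranged from -0.52 to 0.0189 with 1 library left out, the highest without WT replicate 1, and was 0.0321 without both outlying libraries. The cause of these changes was not tested. At this depth and spread simulated changes of 1.5-fold were recovered in 41.8% of genes, so changes of that size can be missed. The simulation had many more changed genes than were called here, so real recovery may be lower.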

Other observations

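The tests of age and handling on the split of libraries, of splits within library sets and of the genes near Furin were chosen after seeing the results they bear on. The 2 gene list hypotheses were prompted by results already seen, but their members' values were not.

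Receptor and translation genes showed no call. The 51 tested T cell receptor alpha V segments had 34 fold changes above 0 (camera adjusted p = 0.243), the 21 beta V segments 12 (camera adjusted p = 0.626), ribosome biogenesis genes 22 of 30 (camera adjusted p = 0.114) and ribosomal protein genes 43 of 79 (camera adjusted p = 0.635). With age as a term beside genotype, edgeR called 42 genes between 7 and 8 weeks, from 2 libraries of 7 weeks. Those libraries also form a library set of their own, so age cannot be told apart from a difference between sets.

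Chance is not excluded for the counts of calls. Of the 56 splits of the 8 libraries into 5 and 3, the real one included, 3 gave as many genes higher (3 genes; highest other 106), 5 gave as many lower (1 gene; highest other 54) and 17 gave as many lists (6 lists; highest other 8). The others with as many genes higher split off WT replicate 2 with Furin KO replicates 2 and 3 (106), or WT replicate 3 with Furin KO replicates 4 and 5 (7). Both groups are library sets, so these splits carry the structure of the samples. For genes higher the share of splits therefore decides nothing about chance. With library set as a factor, 18 splits keep 1 WT library per set, too few for a share under 0.05. The real one gave 8 genes higher (highest other 14), 4 lower (highest other 28) and 6 lists (highest other 7), and as many came from 2, 2 and 4 of the 18, the real one included. The highest other counts of genes came from the split that exchanges WT replicate 2 and Furin KO replicate 3, which called 42 genes against 12.

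The split of WT replicate 2, Furin KO replicate 2 and Furin KO replicate 3 from the other 5 libraries called 160 genes against the genotype's 4, which points to a structure of the samples: these 3 libraries are 1 of the 3 sets with the closest counts. 106 of them were lower in those 3 libraries, among them Fos (log2 -2.63), Jun (-2.49) and Ppp1r15a (-2.27), and none was among the genotype's 4. Age alone does not make this split: these 3 libraries were of 8 weeks, as were WT replicate 3 and Furin KO replicates 4 and 5. At Fos the latter had 944, 801 and 847 CPM, against 144, 204 and 85.8 CPM in WT replicate 2 and Furin KO replicates 2 and 3. Both 7-week libraries lay beyond all 8-week ones at 24 of the 160. Those genes were chosen by the split, so this count leaves an added effect of age open. A difference in handling of the cells before lysis and stimulation in the animal both stay open, since no label records either. The p of the early response list in that split (0.000737 unadjusted, with an estimated correlation) decides nothing between them: the split was singled out by its calls, and genes of that list are among them.

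3 hypotheses were tested. The first was that the higher Ly6a, Socs3, Tbx21 and Iigp1 may reflect a stronger interferon-gamma response. 21 of 21 tested interferon-gamma response genes outside the fixed lists had fold changes above 0, with a median log2 fold change of 0.24, and 0 passed alone. As a set they differed by camera with an estimated correlation (p = 0.0114; 0.0342 adjusted over the 3 hypotheses), and p lay between 0.00236 and 0.0405 over 12 alternatives. Adjusted over the 3 hypotheses as well, these lay between 0.00708 and 0.121, and 10 of the 12 were 0.05 or more, so the call depends on the fit and on single libraries: it held without Furin KO replicate 5 and with 1 surrogate variable. That variable mostly marks Furin KO replicate 5 (0.923, against -0.219 to -0.0298 in the other libraries), so both fits set aside the same library. 2 of the 56 splits, the real one included, gave a p as small, with 0.00169 the lowest of the others. With library set as a factor p was 0.0287 (0.0862 adjusted over the 3 hypotheses), and the lowest of the 17 other splits within sets was 0.0441, too few splits for a share under 0.05. This is a hypothesis found and tested on the same libraries. The fixed type I interferon list, which holds genes of the same families such as Gbp2, was also higher at the preset correlation. No test set these genes apart from that list, so the result does not tell interferon-gamma from other interferons.

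The second was that lower Itgae and Smad7 may reflect a weaker TGF-beta response. Of 10 SMAD target genes outside the fixed lists 5 had fold changes above and 5 below 0. By camera with an estimated correlation p was 0.497, before and after adjustment over the hypotheses. The bound set beforehand, a p of 0.05 or more, would have counted against the hypothesis. It was the wrong bound, since a missed threshold over 10 genes that go both ways excludes nothing, so the question stays open.

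The third was that genes carried along with the Furin allele could differ. Of 165 tested genes within 20 Mb of Furin 2 had an unadjusted p under 0.01 (1.21%), against 96 of 12335 elsewhere (0.778%; one-sided Fisher exact p = 0.372, 0.497 adjusted over the 3 hypotheses), which decides nothing.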
